A study of Rattus norvegicus with 38 samples.

How the data were processed

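Heart tissue of male Sprague-Dawley rats aged 10 weeks was profiled by RNA sequencing in 38 libraries. Per the labels' protocols, rat pups underwent a constriction of the ascending aorta at 1 week of age, which was followed by left ventricular hypertrophy. The same protocol text stands on failing and on healthy libraries, and what the healthy rats underwent is not given in the sources used here. Pieces of the inferior and superior sinoatrial node, the right and left atrium and the left ventricle were taken, and libraries were made with a TruSeq RNA kit, per the labels' protocols. Each title carries a 4-digit code that recurs across regions. The labels do not say that a code marks an animal, and where libraries are not from separate animals the p-values measure only the spread between these libraries. The 8 codes fall into 4 for failing and 4 for healthy hearts, and 0 codes occur in both states, so that any batch tied to the codes cannot be told apart from health state.

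Reads were trimmed with Trimmomatic 0.39 and quantified with kallisto 0.48.0, per the submitters' processing notes. The genome build, the annotation release and the tool that summed transcripts to genes are not given in the sources used here. The deposited gene table holds estimated counts for 24057 genes that are not whole numbers, with library totals from 17406473 to 27355777. The deposited TPM table sums to the same total in every library. The logarithm of the estimated count over the TPM was a gene term plus a library term within 5.8e-13 over the 13474 genes above 0 in every library, so the deposited estimated counts were already scaled for transcript length. The deposited transcript tables gave the same totals and entered no test. All genes carry Ensembl gene IDs and the files do not pair them with names. The reference table used here, of assembly GRCr8, matched 0 of these IDs. The gene lists, the cell type marker lists and the symbol part of the rule for named genes, all fixed before the data were examined, were therefore not applied, and the shares of mitochondrial and haemoglobin genes were not computed. At most 2 IDs in each direction are given, taken from the inferior node by the rest of the rule: the largest fold changes among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and groups that do not overlap. A single gene that passed in another comparison is also given, chosen after its values were seen.

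Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr (count minimum 10, total minimum 15), libraries were scaled with TMM, and groups were compared with the robust quasi-likelihood test of edgeR 4.0.16 in R, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 differences of the first group minus the second, with standard errors derived from the test statistic. The design, with 12 comparisons and each fit restricted to the groups compared, was fixed before the data were examined. Alternatives fixed at the same time were DESeq2 1.42.0, its type of size factors in edgeR, no filter, limma on log2(TPM + 1), 1 fit of all 38 libraries, the code as a replicate block, and each library left out in turn. Alternatives chosen after seeing the data were TPM rescaled by TMM, a per-library trend on relative gene length removed (loess span 0.3), and removal of the 10 most abundant genes. Tests of region-by-health interaction for the pairs of regions other than the node parts were also chosen after seeing the data.

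Whether the codes pair libraries was checked from the correlation, across genes, of same-coded libraries' deviations from their group means. It lay between 0.36 and 0.63 for the node parts in failing hearts, between 0.20 and 0.23 for the superior node and the right atrium, between 0.17 and 0.30 for the inferior node and the right atrium, and between 0.31 and 0.36 for the atria. By the rule that every pair exceeds 0.1, the codes pair the libraries in these 4 comparisons, the pairing coming from the data and the shared codes. The fits without the block, fixed in the design, were kept, and a blocked value stands beside a number of genes it moves by over 1.5 times. Principal components used log2 CPM with a prior count of 2 over 15770 genes. Differences of single values between groups used exact permutation tests, for which the smallest two-sided p with 4 against 4 libraries is 0.0286. No library was identical to another. Over 55 replicate pairs the median squared difference was 4.3 to 82.0 times that of counting error, for genes with a mean count of at least 100.

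The steps were tested on simulated counts with 200 changed genes per comparison. For the inferior node (14379 genes), edgeR recovered 54% of 2-fold and 92% of 4-fold changes, for the superior node (14351 genes) 55% and 92%, and for the left ventricle (13670 genes) 0% and 0%. DESeq2 recovered 11% and 69% in the left ventricle, with 47 false calls.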

Results

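Gene expression was measured in 5 regions of failing and healthy rat hearts: the inferior sinoatrial node (iSAN), the superior sinoatrial node (sSAN), the right atrium (RA), the left atrium (LA) and the left ventricle (LV). The sinoatrial node is the tissue in which the heartbeat starts. Each region had 4 failing and 4 healthy libraries, except for the left ventricle with 4 failing and 2 healthy ones. The series addresses remodelling of both node parts in a rat model of hypertrophic heart disease. Totals per library ranged from 17406473 to 27355777 estimated counts. Libraries are named here by region and the 4-digit code of their label. In the titles, healthy node libraries begin with SB (inferior) or ST (superior), while failing ones begin with iSAN or sSAN. What this difference in naming means is not given in the sources used here.

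Both region and health state separated the libraries, and neither kept to 1 axis. The first principal component held 26.9% of the variance and ordered the node, the atria and the left ventricle, while failing inferior node libraries (-76.3 to -48.7) also lay apart from healthy ones (-47.9 to -17.5) on it. The second held 22.6%, and on it every failing library lay above every healthy library of its own region. In the inferior node the scores were 45.7 ± 14.6 (SD, n = 4) in failing and -30.6 ± 8.0 (SD, n = 4) in healthy libraries. The corresponding means were 38 ± 17.2 and -23.1 ± 4.6 in the superior node, 16.8 ± 20.7 and -62.1 ± 3.5 in the right atrium, and 28.6 ± 23.5 and -59.5 ± 2.6 in the left atrium (SD, n = 4 each). The exact two-sided permutation p was 0.0286 in each of these 4 regions, the smallest the design allows. In the left ventricle the means were 56.3 ± 41.8 (SD, n = 4) and -20.2 ± 2.1 (SD, n = 2), with an exact permutation p of 0.133, where the smallest possible is 0.0667, so the test could not pass the threshold.

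**Figure D1:**
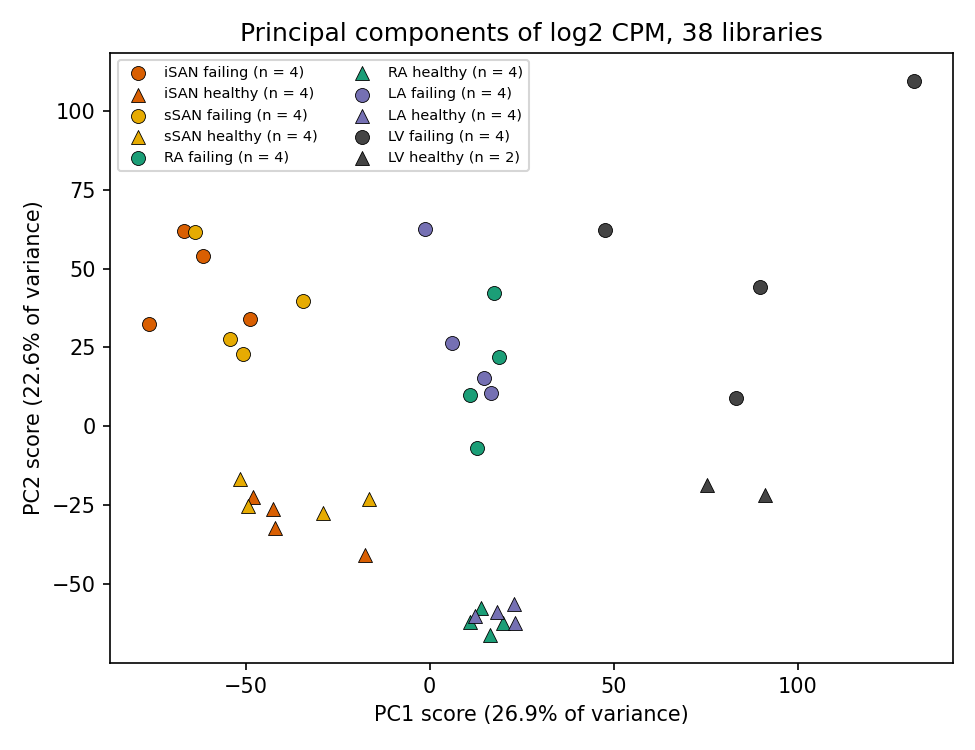
Scores of the 38 libraries on the first (26.9% of variance) and second (22.6%) principal component of log2 CPM, without units; colours are regions, circles failing and triangles healthy hearts, 1 point per library. Failing libraries lie above the healthy libraries of their own region on the second component.

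In the inferior node, 2803 genes were higher and 2730 lower in failing than in healthy hearts, out of 14379 tested with edgeR. Changes of at least 2-fold were seen for 1138 of the higher and 565 of the lower genes. The median size of a passing change was 0.71 on the log2 scale. The gene ENSRNOG00000008015 rose from 4.37 ± 1.01 to 263 ± 145 CPM (SD, n = 4 each), a log2 change of 5.90 (SE 0.44, edgeR adjusted p = 0.00037). The gene ENSRNOG00000029949 rose from 6.02 ± 3.03 to 216 ± 288 CPM (SD, n = 4 each), a log2 change of 5.17 (SE 0.98, edgeR adjusted p = 0.0047), with 646 CPM in the failing library iSAN0508, without which the log2 change was 3.61. The gene ENSRNOG00000025868 fell from 59.1 ± 24.2 to 5.22 ± 3.84 CPM (SD, n = 4 each), a log2 change of -3.50 (SE 0.56, edgeR adjusted p = 0.0024). The gene ENSRNOG00000021943 fell from 5.78 ± 0.728 to 0.422 ± 0.461 CPM (SD, n = 4 each), a log2 change of -3.74 (SE 0.56, edgeR adjusted p = 0.0018) and -4.84 without iSAN0506. On unscaled log2(TPM + 1) values, limma called 1930 genes higher and 953 lower.

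**Figure D2:**
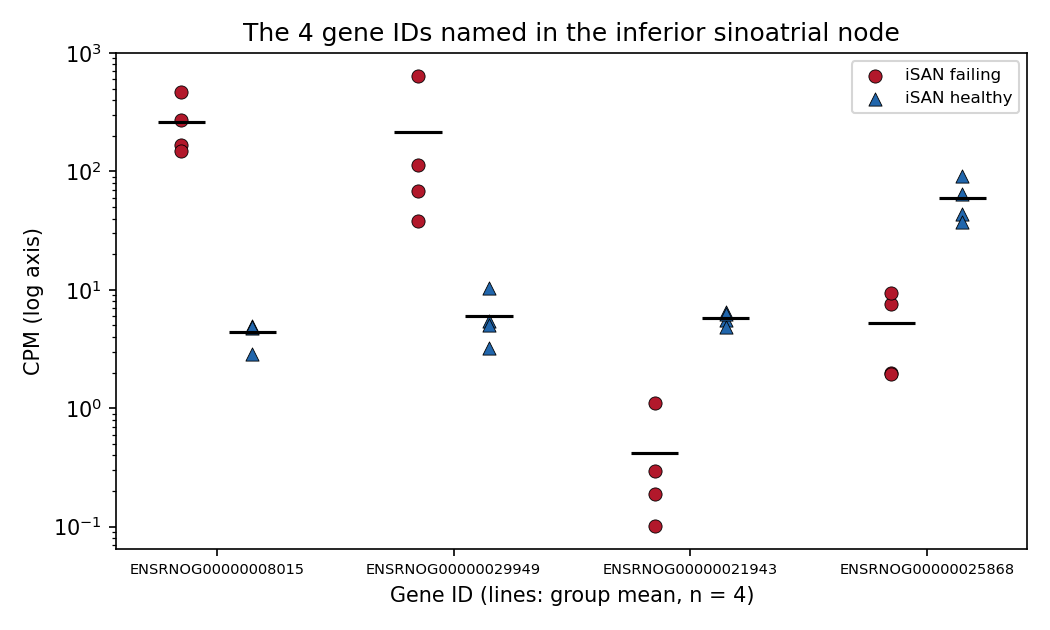
CPM on a log axis of the 4 named genes in the inferior node, 1 point per library (circles failing, triangles healthy), with a line at each group mean (n = 4). The groups do not overlap for any of the 4 genes, and ENSRNOG00000029949 spans 38 to 646 CPM in failing libraries.

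In the superior node, 1280 genes were higher and 654 lower in failing hearts, out of 14351 tested. Changes of at least 2-fold were seen for 689 of the higher and 174 of the lower genes. ENSRNOG00000008015 was higher by 7.48 (log2, SE 0.68, edgeR adjusted p = 0.0017; 8.33 without sSAN0920) and ENSRNOG00000029949 by 4.56 (SE 0.96, edgeR adjusted p = 0.022). ENSRNOG00000025868 was lower, with a log2 change of -3.03 (SE 0.50, edgeR adjusted p = 0.013), while the change of -2.43 of ENSRNOG00000021943 did not pass (SE 0.76, edgeR adjusted p = 0.061) but did so with DESeq2, in the fit of all 38 libraries and with limma on log2(TPM + 1). The log2 change of ENSRNOG00000029949 was 2.88 without sSAN0508, and its call was lost without sSAN0920 and without sSAN1002, with log2 changes of 4.57 and 4.59. The number of genes was sensitive to single libraries: of the total of 1934, it was 368 without healthy sSAN0920, 629 without healthy sSAN1002, 1111 without healthy sSAN0921, 632 without failing sSAN0508 and 645 without failing sSAN0507. DESeq2 called 3293 genes, which included 1933 of the 1934, and limma on unscaled log2(TPM + 1) called 1085 higher and 95 lower.

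The atria had the most genes that passed for health state. Their libraries also varied less, with a biological coefficient of variation of 0.183 (right) and 0.206 (left), against 0.235 and 0.255 in the inferior and superior node. In the fit of all 38 libraries, 4880 genes passed in the right atrium, 5915 in the left and 4790 in the inferior node. In the right atrium 3434 genes were higher and 3223 lower in failing hearts, out of 14011 tested, and 1062 and 655 of them by at least 2-fold. In the left atrium 3461 were higher and 3392 lower, out of 14217, and 1340 and 863 of them by at least 2-fold. ENSRNOG00000008015 was higher by 5.14 (log2, SE 0.47) in the right and 3.87 (SE 0.97) in the left atrium, with edgeR adjusted p of 0.00017 and 0.0096. ENSRNOG00000025868 was lower in both, with log2 changes of -2.92 (SE 0.67) and -4.28 (SE 0.51) and edgeR adjusted p of 0.0063 and 0.00032. They were -3.92 without RA0506 and -4.94 without LA0409. In the left atrium DESeq2 gave no adjusted p for ENSRNOG00000008015 (log2 change 3.89), and the change was 2.08 without LA0409. ENSRNOG00000029949 was higher by 1.07 (SE 0.32, edgeR adjusted p = 0.021) in the right and 2.59 (SE 0.52, edgeR adjusted p = 0.0033) in the left atrium, with 1.83 in the left without LA0507. Its call in the right atrium was lost in the fit of all 38 libraries (log2 change 1.06) and with limma on log2(TPM + 0.1) (0.72). It was also lost without RA0507 (0.96), RA1001 (1.04) or RA1002 (0.89). ENSRNOG00000021943 was lower in the left atrium, with a log2 change of -3.73 (SE 0.42, edgeR adjusted p = 0.00025) and -4.44 without LA0409. Its change of -1.84 in the right did not pass (SE 0.78, edgeR adjusted p = 0.076), but it passed without RA0506 (-2.90), in the fit of all 38 libraries (-1.85) and with limma on log2(TPM + 1) (-2.87). Limma on unscaled log2(TPM + 1) gave 1662 higher and 5121 lower genes in the right atrium, and 1828 higher and 4688 lower in the left. On that scale the median of all genes lay at 0.10 in the inferior node, 0.12 in the superior node, -0.19 in the right atrium and -0.14 in the left atrium, against 0.01, -0.01, 0.02 and 0.01 with TMM. After TMM scaling of the TPM values, chosen after seeing the data, the higher and lower counts were 2637 and 2870, 1079 and 566, 3187 and 3421, and 3238 and 3474 in the same order of regions.

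Genes that changed in more than 1 region mostly did so in the same direction. Over the 13670 genes tested in the 4 regions with 4 libraries per group, 843 were higher and 498 lower in failing hearts in all 4, against 15 and 7 for independent lists, and 0 genes passed in all 4 with differing signs. Between the node parts, 1109 genes were higher in both and 561 lower in both, against 249 and 124 for independent lists, and 0 were opposite. Between the atria, 2523 were higher in both, 2459 lower in both and 21 opposite, against 833, 775 and 1608. The regions were compared through separate libraries, but the same codes recur in each, so these lists are not independent. Of the 1322 genes changed the same way in all 4 regions and tested in the left ventricle, 1284 (97.1%) had the same sign there, against 668 for independent signs. The left ventricles carry codes that also occur among the libraries that selected these genes, so part of this overlap can come from the codes.

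In the left ventricle itself 0 of 13670 genes passed with edgeR, while 1510 had an unadjusted p under 0.05. DESeq2 called 356 genes (280 higher and 76 lower in failing hearts), and limma on unscaled log2(TPM + 1) called 6. The fit of all 38 libraries, which shares the spread of all regions, called 3009. The biological coefficient of variation was 0.401, against 0.235 in the inferior node, 0.255 in the superior node, 0.183 in the right atrium and 0.206 in the left atrium. Without failing LV0507 it was 0.273 and 12 genes passed. On simulated counts with the spread of these 6 libraries and 200 changed genes, edgeR recovered 0% of 4-fold changes. The adjustment is less strict where more genes change, so this does not show that changes of that size were undetectable. ENSRNOG00000008015 had a log2 difference of 2.89 there (SE 1.37, edgeR adjusted p = 0.47), and 1.48 without LV0508. ENSRNOG00000029949 had 3.15 (SE 1.20, edgeR adjusted p = 0.42), passed with DESeq2 (3.19), and had 1.76 without LV0507. ENSRNOG00000025868 had -1.56 (SE 0.64, edgeR adjusted p = 0.44), and ENSRNOG00000021943 was below the filter.

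**Figure D3:**
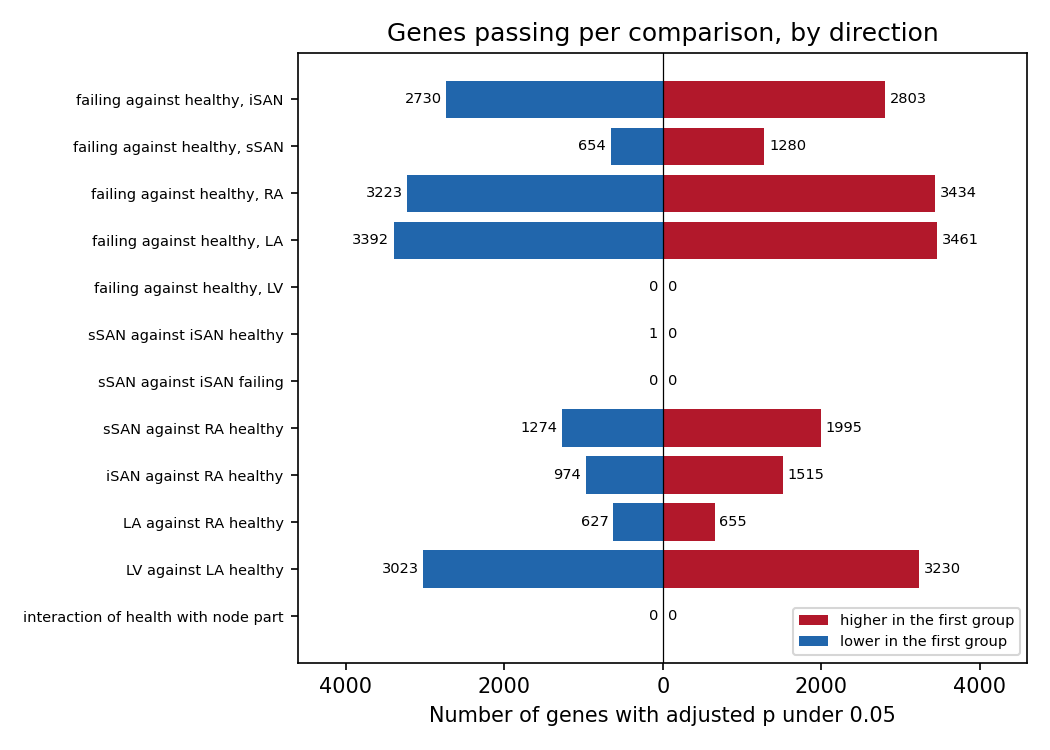
Number of genes with an edgeR adjusted p under 0.05 in each of the 12 comparisons, with bars to the right for genes higher and to the left for genes lower in the group named first. The left atrium has 3461 higher and 3392 lower genes and the left ventricle 0 in either direction.

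Whether the node parts responded differently to disease was tested as the difference between their health effects. With edgeR, 0 of 14918 genes passed, 598 had an unadjusted p under 0.05, and DESeq2 and limma on log2(TPM + 1) also called 0. On simulated counts this test recovered 41% of 2-fold and 79% of 4-fold differences. The larger number of genes in the inferior node was thus not accompanied by a gene that passed as differing in health effect between the parts. This does not show equal effects. A score of the health effect was taken over the 6657 genes that passed in the right atrium, whose libraries carry the same codes. It was 1.05 in the superior and 1.28 in the inferior node (exact two-sided permutation p = 0.0286, the smallest possible). In the test of single genes for other pairs of regions, chosen after seeing the data, 139 of 14920 genes passed for the inferior node and the left atrium (223 with the code as a block), and 97 of 14884 for the superior node and the left atrium.

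Few genes passed between the node parts within a health state. In healthy hearts 1 of 14326 genes passed, with 1463 at an unadjusted p under 0.05, and 2 others passed with the code as a block. The 1 gene, ENSRNOG00000005286, had 0.197 ± 0.147 CPM in the superior and 15 ± 6.72 CPM in the inferior node (SD, n = 4 each), a log2 difference of -6.27 (SE 0.60, edgeR adjusted p = 0.031). Its call was lost with the code as a block (log2 difference -6.22), with limma on log2(TPM + 1) but not on log2(TPM + 0.1) (-3.03 and -5.45), and without any of the 8 libraries other than iSAN0921 (-5.95 to -6.71), with adjusted p up to 0.26. In failing hearts 0 of 14368 genes passed with edgeR, 1130 had an unadjusted p under 0.05, and with the code as a block 1 gene passed. Exchanging iSAN0409 and sSAN0508 between the failing groups, 1 of the 35 splits of these libraries, gave 741 genes. That split keeps both libraries of 2 codes together and parts those of the other codes by region. The 8 splits that part all pairs gave at most 0, but they cannot contain this exchange and so decide nothing about its cause. Every other split gave at most 21 genes, including those that keep every code whole. The 741 was picked as the highest of the 35 splits. The low numbers of the others are thus only weak evidence against differences between codes as its whole cause. DESeq2 called 126 genes in healthy and 41 in failing hearts, and limma on log2(TPM + 1) called 2 and 4. On simulated counts DESeq2 made 29 false calls in healthy and 58 in failing hearts. On simulated counts edgeR recovered 56% of 2-fold and 87% of 4-fold changes between the parts in healthy hearts, and 49% and 85% in failing hearts.

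Both node parts differed from the right atrium in healthy hearts. In the superior node 1995 genes were higher and 1274 lower than in the right atrium, out of 14108, and 907 and 159 of them by at least 2-fold. In the inferior node 1515 were higher and 974 lower, out of 14129, and 756 and 82 of them by at least 2-fold. For the superior node the total of 3269 was 2128, 1937, 2160 and 2115 without RA0920, RA0921, RA1001 and RA1002. For the inferior node the total of 2489 was 1563 without iSAN1001 and 1177 in the fit of all 38 libraries (950 higher and 227 lower). Limma on unscaled log2(TPM + 1) gave 771 higher and 4886 lower genes for the superior node, where the median of all genes moved to -0.31, and 1022 higher and 391 lower for the inferior node. After TMM scaling of the TPM values these were 1686 and 1426, and 1422 and 909.

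The left and right atrium of healthy hearts differed in 1282 of 14024 genes, with 655 higher and 627 lower in the left atrium. At least 2-fold differences were seen for 173 and 151 of them. With the code as a block, which pairs the atria by code, 2692 genes passed, with 1353 higher and 1339 lower, and in the fit of all 38 libraries 225 passed.

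The healthy left ventricle (n = 2) differed from the healthy left atrium (n = 4) in 6253 of 14367 genes, with 3230 higher and 3023 lower in the ventricle. At least 2-fold differences were seen for 946 and 1138 of them. Limma on unscaled log2(TPM + 1) gave 704 higher and 10143 lower genes, with the median of all genes at -0.57, and 3167 and 3093 after TMM scaling of the TPM values, while the fit of all 38 libraries called 3398.

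The 10 most abundant genes took 42.4% ± 14.8 of the counts in failing left ventricles (SD, n = 4), from 28.1% to 61.3%, and 36.2% ± 0.4 in healthy ones (SD, n = 2). In the other regions the group means lay between 18.8% and 31.0%. In the node and the atria the share did not differ beyond the spread between libraries with health state, with exact two-sided permutation p from 0.171 to 0.429. In the left ventricle the exact permutation p was 0.733, where the smallest possible is 0.0667, so the test could not pass the threshold there.

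**Figure D4:**
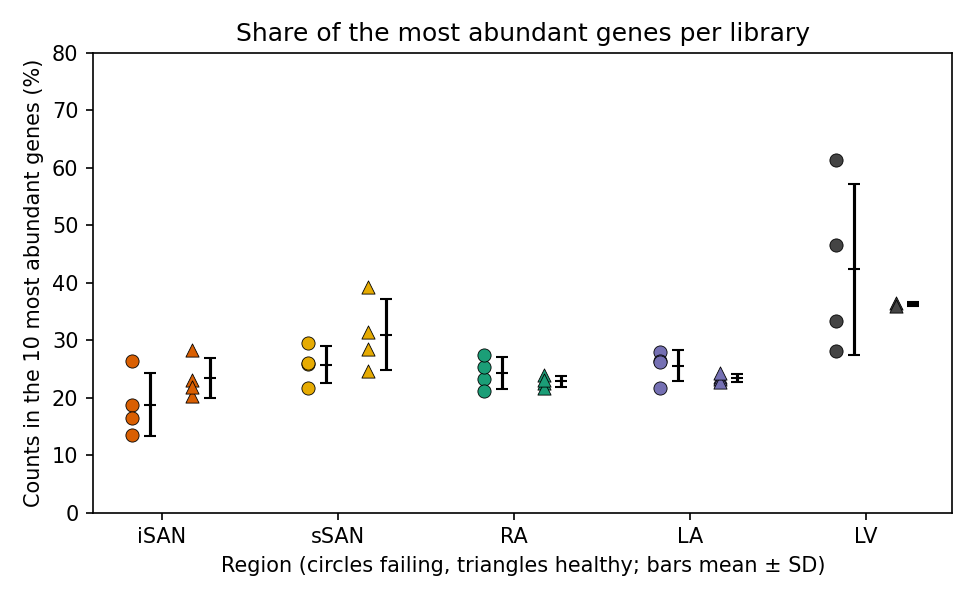
Share of each library's estimated counts, in percent, taken by its 10 most abundant genes, by region; circles are failing and triangles healthy libraries, with bars for mean ± SD. The failing left ventricles range from 28.1% to 61.3%.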

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

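Among the tests of this part, the interactions between regions other than the node parts, the removal of a length trend and of the 10 most abundant genes, the equal depth of left ventricles, the spread between node libraries and the batch that acts differently by region were chosen after the results were seen.

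Differences of the health effect between regions were tested for 10 pairs of regions. The number of genes that passed with edgeR was 139 between the inferior node and the left atrium, 97 between the superior node and the left atrium, 25 between the atria, 17 between the left atrium and the left ventricle, 7 between the right atrium and the left ventricle, and 3 between the inferior node and the right atrium. It was 1 between the inferior node and the left ventricle and 1 between the superior node and the left ventricle, and 0 between the node parts and between the superior node and the right atrium. With the code as a block, 223 genes passed between the inferior node and the left atrium, 89 between the superior node and the left atrium, 24 between the atria and 8 between the inferior node and the right atrium. The 17 and 7 genes between the atria and the left ventricle became 1 and 0. The numbers were 1 and 2 for the inferior and superior node against the left ventricle, 0 between the node parts, and 11 between the superior node and the right atrium.

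Many genes differed with health state in both node parts and both atria. A uniform batch or handling difference that coincides with health state would give equal effects in all regions. The 139 of 14920 genes that differed between the inferior node and the left atrium argue against it as the whole cause for these genes. That pair had the most of the 10 pairs, and 0 genes differed between the node parts or between the superior node and the right atrium. For the other genes a uniform difference stays open. Gene length is argued against as the whole cause of the health differences. The rank correlation across genes of length and log2 change was -0.25, -0.21, -0.35 and -0.30 in the inferior node, superior node, right and left atrium (genes are not independent replicates). Once a length trend was removed, the number of genes was 91.6%, 95.1%, 84.1% and 88.8% of that before. Of the same genes, 77.2%, 79.6%, 69.0% and 75.4% passed, among them 6 and 3 of opposite sign in the right and left atrium. Only genes with a length entered that fit (92.4%, 92.6%, 94.4% and 93.6% of those tested), so genes without one, such as ENSRNOG00000021943, count as not passing in these shares. Without the 10 most abundant genes, 100%, 99.5%, 100% and 99.7% of the number passed. A batch that acts differently by region cannot be told apart from health state, since 0 codes occur in both states, and so heart failure and such a batch both stay open.

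No gene passed in the left ventricle in edgeR. A mislabelled region for failing LV0507 is argued against by its mean correlation with the other failing left ventricles, which exceeded that with the best other region by 0.04. Its 10 most abundant genes took 61.3% of the counts and 11901 of its genes had at least 10 counts, the fewest of the 38 libraries, but low depth is argued against. The most abundant genes were removed and all 6 libraries thinned to the same depth (12943 genes). The biological coefficient of variation without it was then 0.657 of that with it, against 0.972 to 1.09 for the other failing libraries. Leaving it out gave 12 genes and lowered the biological coefficient of variation from 0.401 to 0.273, where leaving out another failing library gave 0.387 to 0.433 and 0 genes. Leaving out a healthy library leaves 1 in that group, so the spread then comes from the failing libraries alone and is no like comparison. The bound written for this test took fewer than 100 genes as evidence against 1 far library. With 200 changed genes simulated, however, the 5 remaining libraries (13633 genes) recovered 15% of 2-fold and 75% of 4-fold changes. Many changes near 2-fold could be missed, and a far library stays open as a candidate explanation. A small health effect is undecided as well. On the second principal component the left ventricle means were 56.3 ± 41.8 (failing, SD, n = 4) and -20.2 ± 2.1 (healthy, SD, n = 2). These were no closer together than 45.7 and -30.6 in the inferior node. The failing mean includes LV0507 itself at 109.6, however, with 9.1, 44.3 and 62.1 in LV0409, LV0506 and LV0508. The means therefore do not decide the size of the effect. Only 2 healthy left ventricles were available.

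Fewer genes passed in the superior than in the inferior node. The common biological coefficient of variation was 1.09 times as large in the superior node, under the bound of 1.1 written for a larger spread, so this explanation is undecided. A score of the health effect was taken over the 6657 genes that passed in the right atrium (3434 higher and 3223 lower), whose libraries carry the same codes. It describes these genes as a set, not the change of a single gene. In the superior node it was 0.819 of that in the inferior node (1.05 against 1.28 on the log2 scale). The exact two-sided permutation p for the difference between codes was 0.0286, the smallest possible. The bound written for a smaller effect was a ratio under 0.8, so a smaller health effect in the superior node may contribute but is also undecided.

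In 69 groups of 4 libraries or values tested, 5 had a library far from the other 3, where chance gives about 1 in 20. Healthy iSAN1001 had 14394 genes with at least 10 counts, against 14181 to 14216 in the others. ENSRNOG00000008015 had 2.86 CPM in healthy iSAN0921, against 4.80 to 5.00. ENSRNOG00000029949 had 645.6 CPM in failing iSAN0508, against 38 to 112.6. ENSRNOG00000005286 had 4.90 CPM in healthy iSAN0921, against 18.0 to 18.7. The mean log2 CPM of genes higher in the inferior node than in the right atrium was 1.40 in healthy LA0920, against 1.25 to 1.26.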

How the results depend on the processing

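The alternatives fixed before the data were examined left at least 2883 genes with a health effect in the inferior node and in each atrium. For each number of genes listed here as moved, the cause was not tested unless stated. DESeq2 gave 3293 genes for health in the superior node, 356 in the left ventricle, and 126 and 41 between the node parts of healthy and failing hearts. Limma on unscaled log2(TPM + 1) gave 2883 for health in the inferior node, 1180 in the superior node and 6 in the left ventricle, 2 and 4 between the node parts of healthy and failing hearts, 5657 and 1413 for the superior and inferior node against the right atrium, and 10847 for the left ventricle against the left atrium. The fit of all 38 libraries gave 3009 for health in the left ventricle, 5 and 5 between the node parts, 1177 for the inferior node against the right atrium, 225 between the atria and 3398 for the left ventricle against the left atrium; its construction replaces the spread of the groups compared by that of all groups. Without the filter, 3 and 3 genes passed between the node parts.

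With the code as a replicate block, 2692 genes passed between the atria, 1 between the node parts of failing hearts and 2 between those of healthy hearts. Among the 12 comparisons fixed before, it moved no other number of genes by over 1.5 times, but it did so for 6 of the 10 tests of interaction between regions, given with those tests. In healthy hearts the codes did not pair the node parts, with correlations from -0.06 to 0.54 and 2 of 4 libraries closest to their own code, nor the left ventricle with the left atrium, with 2 pairs. Of the alternatives chosen after seeing the data, TPM on the TMM scale gave 0 and 2 genes between the node parts of healthy and failing hearts, and removal of the length trend gave 0 in healthy hearts.

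Leaving out 1 library gave 368 (without healthy sSAN0920) to 1987 genes for health in the superior node, 0 to 12 (without failing LV0507) in the left ventricle, 0 to 2 between the healthy node parts, 1937 to 3629 for the superior and 1563 to 3149 for the inferior node against the right atrium. Over 20 results of named genes, 330 alternatives gave the same direction in every case, with the same side of the threshold in 303, a lost call or no adjusted p in 18 and a gained call in 9. The gene lists, with their own alternatives, and the symbol-based naming were not run because the files hold IDs only. Depth was similar between groups. Over genes with a mean count of at least 100, the spread between replicate libraries exceeded counting error. Genes with fewer counts were not measured this way, and what limited the calls was not tested.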

Other observations

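In this part, the tests of the spread of libraries around their group and of lists made without a code were chosen after the results were seen. The region profiles were lists of genes with at least 2-fold higher expression in 1 healthy region, defined from these libraries and tested in regions that did not define them, and they were chosen after the comparisons were seen but before their own values were computed. The healthy libraries tested carry the codes of those that defined the lists, and same-coded libraries deviate together, so these differences and their p-values may be inflated (-0.36 and 0.17 included). The lists were therefore made again without each healthy code in turn and tested on the library of that code. Their 7 tests and the 4 tests of spread are two-sided permutation tests over all regroupings, called exact here for that reason.

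Genes higher in the right atrium than in the inferior node (82 genes) had a mean log2 CPM of 2.17 ± 0.16 in failing and 2.53 ± 0.12 in healthy left atria (SD, n = 4 each), a difference of -0.36 (exact permutation p = 0.0286, adjusted p = 0.10). Of 75 tested there, 28 were lower and 18 higher in failing hearts. In the superior node the difference was -0.35 (exact permutation p = 0.257, adjusted p = 0.36). Genes higher in the inferior node than in the right atrium (756 genes) differed by 0.32 in the left atrium (exact permutation p = 0.0571, adjusted p = 0.133) and by 0.26 in the superior node (exact permutation p = 0.229, adjusted p = 0.36). Genes higher in the left ventricle than in the left atrium (946 genes) differed by 0.17 in the right atrium, with 3.32 ± 0.03 in failing and 3.15 ± 0.06 in healthy libraries (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.10). Of 861 tested there, 260 were higher and 116 lower in failing hearts. They differed by -0.01 in the inferior node and -0.02 in the superior node (exact permutation p = 0.914 and 0.657), with 123 higher and 186 lower in failing hearts in the inferior and 58 higher and 46 lower in the superior node.

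A hypothesis is that the failing right atrium may shift towards the ventricular profile (0.17). With lists made without its own code, each of the 4 healthy right atria lay below all failing ones, with differences from 0.11 to 0.27, where a list that left 1 left ventricle took it to vary like the left atria. Whether the failing left atrium loses part of the atrial profile (-0.36) stays open, since with such lists 3 of the 4 healthy libraries lay above all failing ones (differences from -0.60 to -0.28, 40 to 93 genes). For its shift towards the node profile (0.32) the differences were 0.24 to 0.37, with 4 of 4 healthy libraries below all failing ones. In the superior node such lists gave -1.11 to 0.48 for the atrial profile (-0.35), with 3 of 4 healthy libraries above all failing ones, and 0.06 to 0.70 for the node profile (0.26), with 2 of 4 below, so neither is decided there. For the ventricular profile they gave -0.19 to 0.10 in the inferior and -0.12 to 0.05 in the superior node. None of these differences passed after adjustment over the 7 tests. Whether the node parts shift towards the ventricular profile is undecided, since means near 0 (-0.01 and -0.02) over genes that go both ways decide nothing. The bounds written for these tests took a p of 0.05 or more as evidence against a shift. They were not applied, since a p that misses the threshold does not show that values did not differ, and the 5 differences concerned stay open.

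A second hypothesis is that failing libraries may vary more than healthy ones. The distance of a library to the mean of the others in its group was 1.23 times as large in failing as in healthy right atria and 1.33 times in left atria (exact permutation p = 0.0286 each, adjusted p = 0.0572). The ratio was 1.06 in the inferior node (exact permutation p = 0.657) and 0.976 in the superior node (exact permutation p = 0.686). The distances of a group are taken from the same libraries and depend on each other. These p-values may therefore be too small, and the adjusted p of the atria did not pass the threshold.

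Each comparison of 4 against 4 libraries was set against all 35 splits of its libraries. For the health effects, 1 split, the real one, gave as many genes in the inferior node (5533, highest other 2), superior node (1934, highest other 1), right atrium (6657, highest other 2) and left atrium (6853, highest other 1), so a chance regrouping of these libraries is argued against. The same held for the superior node against the right atrium (3269, highest other 0), the inferior node against the right atrium (2489, highest other 1) and the left against the right atrium (1282, highest other 29), and the highest other number among the 8 splits that part all pairs was 0 in each. In each case 1 of 35 is the smallest share possible. Other splits mix the groups compared, which raises the spread within groups, so their low numbers add nothing further. The comparisons share codes and are not separate evidence. For the difference of health effects between node parts, the states of the codes were regrouped, and all 35 splits gave 0 genes. Between the healthy node parts 4 of 35 splits gave at least the 1 gene found, so chance stays open.

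Between the failing node parts the real split gave 0 genes, which all 35 splits reached, and 1 of the others gave 741, with 21 for the next. That split set iSAN0409 with sSAN0409, sSAN0506 and sSAN0507, and sSAN0508 with iSAN0506, iSAN0507 and iSAN0508. It keeps the libraries of each of these 2 exchanged codes together and parts those of the other codes by region. The splits that keep every code whole gave at most 21. So did the other splits that set the same 2 codes against each other, which differences between codes alone would leave with similar numbers. The 741 was picked as the highest of the 35 splits, so this is only weak evidence against codes as its whole cause. Among the 8 splits that part all pairs the highest number was 0, but these cannot contain the exchange and decide nothing about its cause. Same-coded libraries deviated together (correlations from 0.36 to 0.63), so differences between codes may contribute. A crossed or imprecise dissection of iSAN0409 and sSAN0508 is another possible explanation and was not tested apart from the codes.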
